A study of Homo sapiens with 2 samples.

How the data were processed

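HUVEC were grown in medium with 2% serum, per the labels' protocols, and whether serum was added back during treatment is not given in the sources used here. Extracellular vesicles were collected from the medium of HUVEC treated with vehicle or 100 nM FVIIa for 24 h after 2 h without serum, by spinning at 21000 g for 1 h, per the labels' protocols. RNA was isolated with a kit for small RNA, per the labels' protocols. The 2 samples were assigned to their groups by the agent named in the labels, 1 per group.

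The authors deposited whole-number count tables of 1370 hairpins and 384 mature miRNAs, with 1 column per library. The submitters' processing notes name bcl2fastq 2.19.0, Trim Galore 0.6.6, FastQC 0.11.9, Bowtie 1.3.0, SAMtools 1.12 and the build GRCh37, with no role or order. The mismatches allowed, the treatment of reads with several matches and the strand rule are not given in the sources used here. The column names carry a mark for reverse complement, and what it refers to is not given in the sources used here, so it is not known whether both tables count the same strand. The authors also deposited normalized values (unit: signal) for both tables, each equal to the count times 1 constant per column. The constants were 2.88 and 7.16 per hairpin read for vehicle and FVIIa, and 1128 and 2340 per mature read. They equal count shares of a library size multiplied by edgeR's TMM factors, as recomputed from the counts (hairpin factors 1.52 and 0.66). All columns of per-sample values were used.

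Some rows shared reads. The rows of mir-374b and mir-374c had 580 counts each in vehicle and 251 each in FVIIa, and those of mir-423 and mir-3184 had 1533 and 1525 in vehicle. The totals are therefore sums over rows, in which a read can count more than 1 time, and near-identical copies and overlapping hairpins are uncertain.

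The share of a row was its count over the total of its table and library. Ratios are FVIIa over vehicle shares, with exact conditional binomial 95% intervals, and shares carry exact Clopper-Pearson 95% intervals. Reads carry no molecular identifiers that are known here, so intervals and floors cover counting error only. A row was called higher or lower when its ratio was at least 2-fold with an interval excluding 1, among rows with at least 20 reads in a library, and 0 counts were taken as 3 counts for a bound. With 1 library per group no p-value between the conditions was computed. List medians used log2 of CPM (count over total times 1e+06) plus a pseudocount of 1, over members with at least 20 reads, and were placed among 10000 random lists of the same size matched on mean abundance in 10 bins. A further match used 3 groups of GC content with 5 abundance bins in each, over 241 summed hairpins with a sequence. Lists with fewer than 3 measured members got no percentile.

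The groups, the rule, the 23 lists, the settings to compare and the rule for named miRNAs were fixed before the data were examined. However, miR-10a-5p was named because later work on these vesicles is known to have followed it. Its naming was therefore not independent of these data. The lists were endothelial-enriched, the mir-10, mir-99, mir-100 and mir-125 family, inflammation-restraining, inflammation-induced, barrier and junction, tissue factor and coagulation, mir-17-92 and paralogues, let-7 and mir-98, mir-23, mir-27 and mir-24, mir-15 and mir-16, mir-30, mir-29, mir-181, hypoxia, the 14q32 cluster, structured RNA fragments, and markers of erythroid, leukocyte and platelet, smooth muscle, fibroblast, epithelial, liver and neuronal cells. Named were miR-10a-5p, the 10 largest and 10 smallest mature ratios and the 5 largest and 5 smallest hairpin ratios among called rows with at least 100 reads (no mature row and 1 higher hairpin qualified), the 10 most abundant of each table, and up to 4 members of each list with the highest mean share. Other names, among them mir-411, mir-221, mir-222, mir-146a, mir-24, let-7b, mir-30b, mir-106b, mir-19a in its cluster, mir-26b, mir-375, mir-5100 and miR-4477a, were chosen after their values were seen. The lists had been planned for the mature table, and because few mature rows had reads they were also run on the hairpins, a choice made after the data were seen, as were the total without 5 hairpins and the match of random lists on GC content.

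Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors and upper-quartile factors (R 4.3.3), the total without the 10 most abundant rows, the deposited values, read minimums of 100 or none, folds of 1.5 and 4, an interval wholly beyond 2-fold, and a pseudocount of 10. The upper-quartile factors rest on low counts. In the FVIIa library 199 of 1370 hairpins had at least 10 reads, so the upper quartile lay below 10 reads. Of 384 mature rows, 37 had at least 2 reads there, so the mature upper quartile lay below 2 reads. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. GC content came from hairpin sequences matched by name in another build of the genome than the authors', so no coordinates are given, and 256 of the 263 hairpins had a sequence. It is that of the whole hairpin, not of the reads. The comparison of hairpins with other non-coding RNAs used ribosomal, small nuclear, small nucleolar, mitochondrial and other annotated RNAs, and nuclear tRNA sequences were not used here.

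The calls were tested on simulated data with the hairpin table's means and totals for FVIIa against vehicle, 1370 hairpins with 200 changed. Simulated 0.25-fold and 0.4-fold changes were recovered for 100% of hairpins, 4-fold changes for 90% and 2.5-fold changes for 2%. The true share ratio of the 2.5-fold set was only 1.46 because raised abundant hairpins had enlarged the total. The larger total also took the 0.25-fold and 0.4-fold sets to true share ratios of 0.15 and 0.23, so their recovery overstates sensitivity. For the same reason 27.8% of unchanged hairpins were called. With no change simulated, 3 of 224 hairpins were called. Intervals held the true share ratio for 96.7% of hairpins. The simulation held counting error only, so it does not cover variation between preparations.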

Results

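Small RNA was sequenced from extracellular vesicles released by human umbilical vein endothelial cells (HUVEC), primary cells of the vein wall that are widely used as a model of endothelium. The cells had been kept for 24 h with control vehicle or with 100 nM activated factor VII (FVIIa), a serine protease that starts coagulation together with tissue factor. There was 1 library per group, each made from 1000000000 vesicles per the labels, so no difference between the conditions has a replicate check. Reads were counted against miRNA hairpins, with totals of 228876 counts for vehicle and 211782 for FVIIa. Reads were also counted against mature miRNAs, with totals of only 1173 and 323 counts. The account therefore rests mainly on the hairpins, in which the arms of a hairpin cannot be told apart. Values are shares of a library, not amounts per vesicle, and all intervals are 95% intervals for counting error only.

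The 1st comparison asked how the make-up of the vesicle miRNA differed between the libraries. A single hairpin, mir-10a, led both libraries, and it held 18.1% of hairpin counts in the vehicle library (exact interval 17.96 to 18.28) and 44.9% in the FVIIa library (44.7 to 45.2). The 2nd most abundant hairpin over both libraries was mir-21, a miRNA abundant in many cell types, with 13.1% and 12.9%. The vehicle library also held large shares of mir-1260b and mir-1260a, with 22880 and 15871 counts, whereas the FVIIa library held 691 and 874. The 10 most abundant hairpins of each library took 68.5% of vehicle counts (68.4 to 68.7) and 85.3% of FVIIa counts (85.2 to 85.5). The 50 most abundant took 89.6% and 96.1%. At least 1 read was counted for 1289 hairpins in the vehicle library and for 758 in the FVIIa library, and at least 100 reads for 110 and 70. A hairpin with 0 counts could have held up to 0.00131% of the vehicle library and 0.00142% of the FVIIa library.

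**Figure D1:**
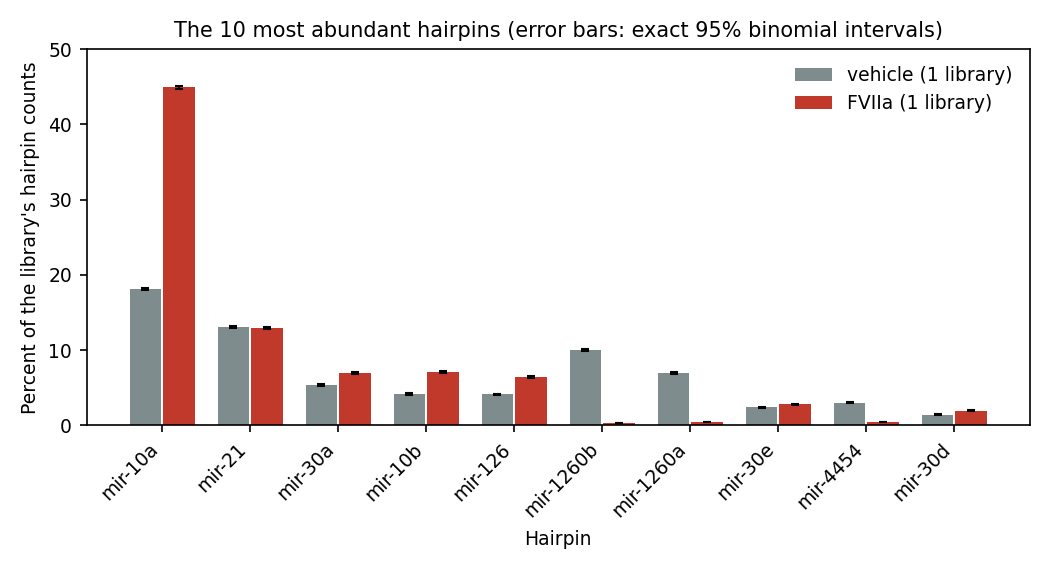
Share of hairpin counts (y axis, percent of the library, error bars for exact 95% intervals) for the 10 hairpins with the highest mean share (x axis) in the vehicle and FVIIa libraries, 1 library each. The share of mir-10a is 18.1% in vehicle and 44.9% in FVIIa, while mir-1260b has 22880 counts in vehicle and 691 in FVIIa.

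The next comparison asked which hairpins took a larger or smaller share with FVIIa. The most abundant one, mir-10a, known to restrain NF-kB signalling in endothelium, had a 2.48-fold higher share with FVIIa (interval 2.45 to 2.51). The closely related mir-10b was 1.71-fold higher (1.67 to 1.75), and mir-126, an endothelial hairpin needed for vascular integrity, was 1.57-fold higher (1.52 to 1.61), both short of the 2-fold rule. The share of mir-21 had a ratio of 0.99 (0.97 to 1.00). The lowest ratios among hairpins with at least 100 reads were those of mir-4286, 96.2-fold lower (58.1 to 172), mir-1260b, 30.6-fold lower (28.4 to 33.1), mir-320a, 20.7-fold lower (12.4 to 37.4), mir-4321, 18.4-fold lower (12.2 to 29.1), and mir-1260a, 16.8-fold lower (15.7 to 18.01).

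Of 263 hairpins with at least 20 reads in a library, 2 were higher, 180 lower and 81 neither under a rule of at least 2-fold with an interval that excludes 1. The 2 higher ones were mir-10a and mir-411, the latter with 7 and 26 counts (ratio 4.01, 1.70 to 10.95). This split depended strongly on the scaling. On the authors' deposited normalized scale, where FVIIa values are 2.30-fold higher relative to vehicle than by total count, 42 hairpins were higher and 79 lower. With DESeq2 size factors the split was 46 to 70, with a shift of 1.35 in log2. With upper-quartile scaling it was 82 to 35, with a shift of 2.00, a factor that rests on an upper quartile below 10 reads in the FVIIa library. With the 10 most abundant hairpins left out of the total it was 32 to 96, with a shift of 1.00. On the deposited scale mir-21 was 2.27-fold higher, mir-10b 3.93-fold higher, mir-126 3.60-fold higher and mir-10a 5.70-fold higher.

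Each scaling multiplies all ratios by 1 factor, so the 35 hairpins lower with the upper-quartile factor, the largest tried, were lower under every other factor as well, 16 of them with at least 100 reads. These 35 had a median GC content of 67.2% (33 with a sequence), against 54.0% for the other 223 tested hairpins with one, and across tested hairpins the median log2 ratio by total count was -0.84 in the lowest and -2.47 in the highest of 3 GC groups. Several of the strongest falls did not have high GC content. It was 44.1% for mir-4286, 50.9% for mir-222, 53.4% for mir-1260a and 56.2% for mir-1260b. For mir-320a it was 59.8% and for mir-5100 62.2%. Besides the 5 lowest ratios named above, the 16 held mir-210, mir-222, mir-93, mir-26b, mir-375, mir-5100 and others. The smallest factor came from leaving mir-1260a, mir-1260b, mir-4454, mir-5100 and mir-4286 out of the total, a setting chosen after the data were seen. With it mir-411 alone was higher, and mir-10a reached 1.959-fold, just under the rule.

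The abundance of mir-10a relative to other hairpins needs no scaling between libraries, but a GC bias between the libraries could still change it. The GC content is 39.1% for mir-10a, 40% for mir-10b, 48.6% for mir-21 and 52.9% for mir-126. Per count of mir-21 there were 1.38 counts of mir-10a in the vehicle library and 3.48 in the FVIIa library, a 2.51-fold difference (2.46 to 2.56). The same fold was 1.91 against mir-30a, 1.58 against mir-126 (1.54 to 1.63) and 1.45 against mir-10b (1.41 to 1.49). Because mir-10a and mir-10b have nearly identical mature sequences, reads of one can be counted under the other.

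**Figure D2:**
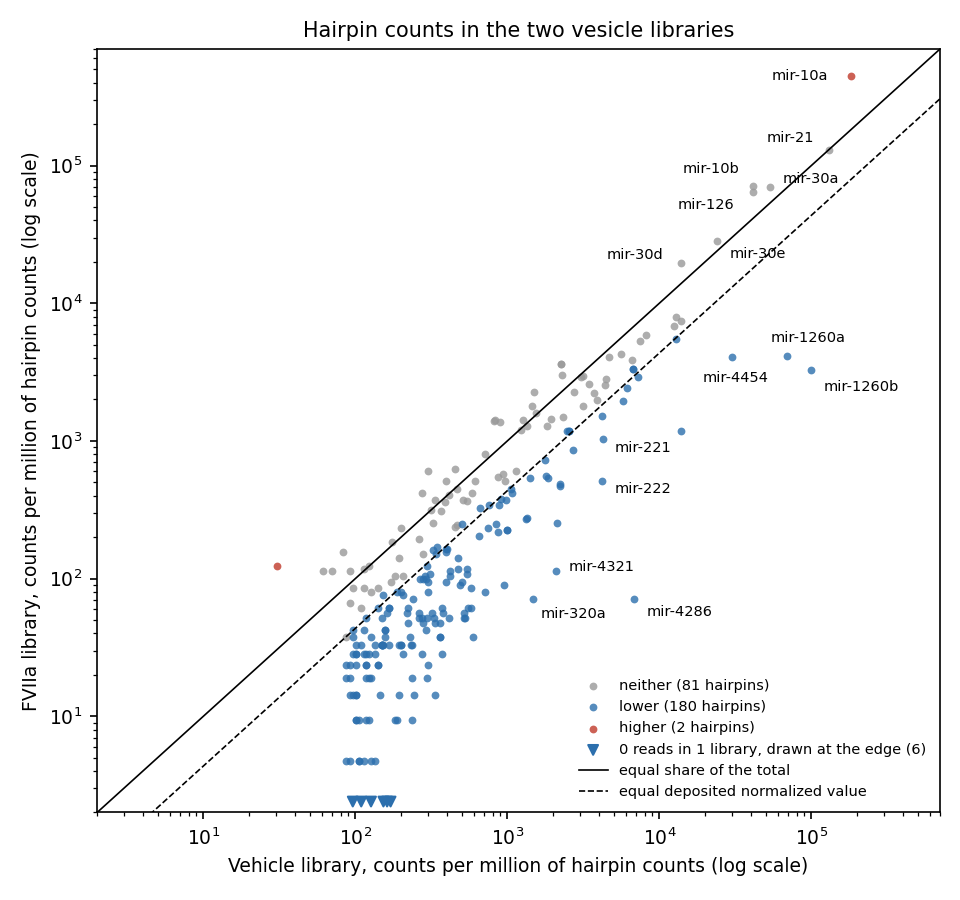
Hairpin counts in the vehicle library (x axis) and the FVIIa library (y axis) as count shares on log axes, 1 point per hairpin with at least 20 reads in a library, with triangles at the edge for 0 reads. The solid line marks equal shares and the dashed line equal values on the authors' deposited scale. By total count, 2 hairpins lie on the higher side and 180 on the lower side of the 2-fold rule, and on the deposited scale the split is 42 to 79.

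The following comparison asked about groups of hairpins fixed before the data were examined, with copies of a hairpin summed. The groups overlap, so their splits are not separate findings. The endothelial-enriched, mir-10 family and inflammation-restraining lists all hold mir-10a, the 1 member higher by total count in each. The endothelial-enriched, inflammation-restraining, barrier and coagulation lists all hold mir-126, which was among the members higher on the deposited scale in each. Among 249 summed hairpins, 174 were lower and 2 higher, and the median log2 ratio was -1.69. With upper-quartile factors mir-222, mir-93, mir-210 and mir-320a were the only list members still lower, and with the total without 5 hairpins mir-411 was the only one higher. Of 7 measured endothelial-enriched hairpins, 1 (mir-10a) was higher, 2 were lower and 4 neither, while on the deposited scale 3 were higher and 1 lower. The lower ones, a pair known to restrain angiogenesis, were mir-222, 8.11-fold lower (6.64 to 9.98) and 3.53-fold lower on the deposited scale, and mir-221, 4.11-fold lower (3.55 to 4.79) but 1.79-fold lower and not called on the deposited scale. The split of this list was 5 higher and 1 lower with upper-quartile factors, and 0 higher and 4 lower with the total without 5 hairpins. The group as a whole took 29.4% of vehicle counts and 59.8% of FVIIa counts, most of it mir-10a. Its median log2 ratio of -0.91 lay at percentile 29.7 of 10000 random lists matched on abundance, and at 73.8 with no read minimum. The median was 0.29 on the deposited scale and 1.09 with upper-quartile factors.

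Of 7 members of the mir-10, mir-99, mir-100 and mir-125 family, 1 (mir-10a again) was higher and 0 lower (median -0.40, percentile 83.1), and on the deposited scale 3 were higher and 0 lower. The split was 7 higher and 0 lower with upper-quartile factors, and 0 higher and 3 lower with the total without 5 hairpins. Its mir-100 had 3194 and 1571 counts (ratio 0.53) and its mir-125b 1641 and 776 (0.51). Of 7 inflammation-restraining hairpins, 1 (mir-10a again) was higher and 2 lower (median -0.78, percentile 55.1), with mir-181b 2.41-fold lower (2.28 to 2.55) and mir-146a, a feedback brake on NF-kB signalling, 4.10-fold lower (1.77 to 11.03) on 31 and 7 counts. On the deposited scale 2 of these were higher and 0 lower, with upper-quartile factors 5 and 0, and with the total without 5 hairpins 0 and 4. Their median was 0.42 on the deposited scale and 1.22 with upper-quartile factors. Their percentile was 29.9 with the match on GC content as well and 88.2 with no read minimum. Of 4 inflammation-induced hairpins, mir-21, mir-217, mir-92a and mir-34a, 0 were higher and 0 lower (median -0.30, percentile 78.1), while 2 were higher on the deposited scale.

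Of 6 hairpins linked to endothelial junctions and barrier, mir-101 was 2.49-fold lower (2.08 to 2.98) and 5 were neither (median -0.49, percentile 70.2), against 3 higher and 0 lower on the deposited scale. Of 6 hairpins linked to tissue factor and coagulation, 4 were lower and 0 higher (median -1.20, percentile 40.9), against 1 lower and 2 higher on the deposited scale. The lower ones were mir-93, 8.28-fold lower (6.24 to 11.2), mir-19b, 3.33-fold lower, mir-19a, 2.61-fold lower, and mir-106b, 2.03-fold lower. On the deposited scale mir-93 alone of these stayed lower, at 3.60-fold, and mir-106b turned to a ratio of 1.13. The mir-17-92 cluster and its paralogues, which share these 4, had 4 of 9 lower and 0 higher (median -0.93, percentile 78.9), against 1 lower and 4 higher on the deposited scale. The hypoxia-induced mir-210 was 15.8-fold lower (7.82 to 37.4) on 137 and 8 counts, and 3.95-fold lower with upper-quartile factors.

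Of 9 let-7 and mir-98 hairpins, 4 were lower and 0 higher (median -0.92, percentile 90.1), including let-7b, 4.63-fold lower (2.99 to 7.42), and on the deposited scale 1 was lower and 0 higher. The let-7 split turned to 5 higher and 0 lower with upper-quartile factors, and it was 0 higher and 7 lower with the total without 5 hairpins. In the mir-181 family 3 of 4 were lower (median -1.47, percentile 32.4), and on the deposited scale 0 were. In the mir-23, mir-27 and mir-24 clusters, 1 of 5 was lower, mir-24, 3.07-fold lower (median -0.64, percentile 74.9), against 0 lower and 2 higher on the deposited scale. That value sums mir-24-1, with 64 and 10 counts, and mir-24-2, with 42 and 22 and not called by itself, while mir-3074, which overlaps mir-24-1, held 1310 and 410 counts, so the level of mir-24 is uncertain. In the mir-30 family mir-30a was at 1.301, mir-30d at 1.40 and mir-30e at 1.18, while mir-30b was lower on 21 and 3 counts (median 0.23, percentile 95.4). On the deposited scale 4 of the 5 mir-30 hairpins were higher and 0 lower. Of 2 mir-29 hairpins, 1 was lower by total count and 0 on the deposited scale, where 1 was higher. With upper-quartile factors the splits, higher to lower, were 4 to 0 for inflammation-induced, 5 to 0 for barrier, 2 to 1 for coagulation, 5 to 1 for mir-17-92, 4 to 0 for mir-23, mir-27 and mir-24, 4 to 0 for mir-30 and 1 to 0 for mir-181 hairpins. With the total without 5 hairpins they were 0 to 0, 0 to 3, 0 to 4, 0 to 5, 0 to 2, 0 to 1 and 0 to 4 in the same order.

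By total count, the 2 lists outside the central 95% of random lists matched on abundance were the mir-15 and mir-16 family and the imprinted 14q32 cluster. With 14 lists given a percentile, some can fall outside by chance. Random lists drew hairpins independently, whereas members of a family or cluster may vary together. The median of the mir-15 and mir-16 family was -0.04 (percentile 98.8), with 1 of 7 lower, and it turned positive at 1.16 on the deposited scale, where 5 were higher. With upper-quartile factors 6 of its 7 and 7 of the 16 14q32 hairpins were higher and 0 of either lower. In that family mir-16 had a ratio of 1.52 (1.36 to 1.70). The 14q32 cluster had 9 of 16 lower and 1 higher (median -1.24, percentile 99.5), against 1 lower and 3 higher on the deposited scale, where the median was -0.05. Its mir-127 was 3.35-fold lower (2.46 to 4.63) but 1.46-fold lower and not called on the deposited scale. All 6 measured hairpins of the list drawn up, from background knowledge, as resembling fragments of other structured RNAs were lower (median -2.25, percentile 31.9), among them mir-4454, 7.35-fold lower (6.85 to 7.90), and 2 of them were lower on the deposited scale. The others were mir-3648, mir-320a, mir-484, mir-320b and mir-4508, and whether reads of these 6 are such fragments is not known here. The list did not hold mir-1260a, mir-1260b, mir-5100 or mir-4286. No list lay below percentile 2.5. With random lists matched on GC content as well, a setting chosen after the data were seen, the mir-15 and mir-16 family was at percentile 99.5, while 14q32 was at 70.7, let-7 and mir-98 at 36.6 and mir-181 at 4.10. The 14q32 cluster was at percentile 97.485, inside the central 95%, with upper-quartile factors, and at a minimum of 100 reads the mir-15 and mir-16 family was at 88.9 and 14q32 had too few members.

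Hairpins typical of other cell types were few. Erythroid ones had 11 and 0 counts in vehicle and FVIIa, smooth muscle ones 19 and 5, neuronal ones 10 and 0, and the liver one 0 and 0. Leukocyte and platelet ones had 114 and 134 counts, nearly all mir-342 with 103 and 132, which was higher on the deposited scale but not by total count. Fibroblast ones had 218 and 78 counts, with mir-199a 3.01-fold lower by total count, and epithelial ones 106 and 40, with mir-203a 2.43-fold lower. Neither mir-199a nor mir-203a was called on the deposited scale.

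**Figure D3:**
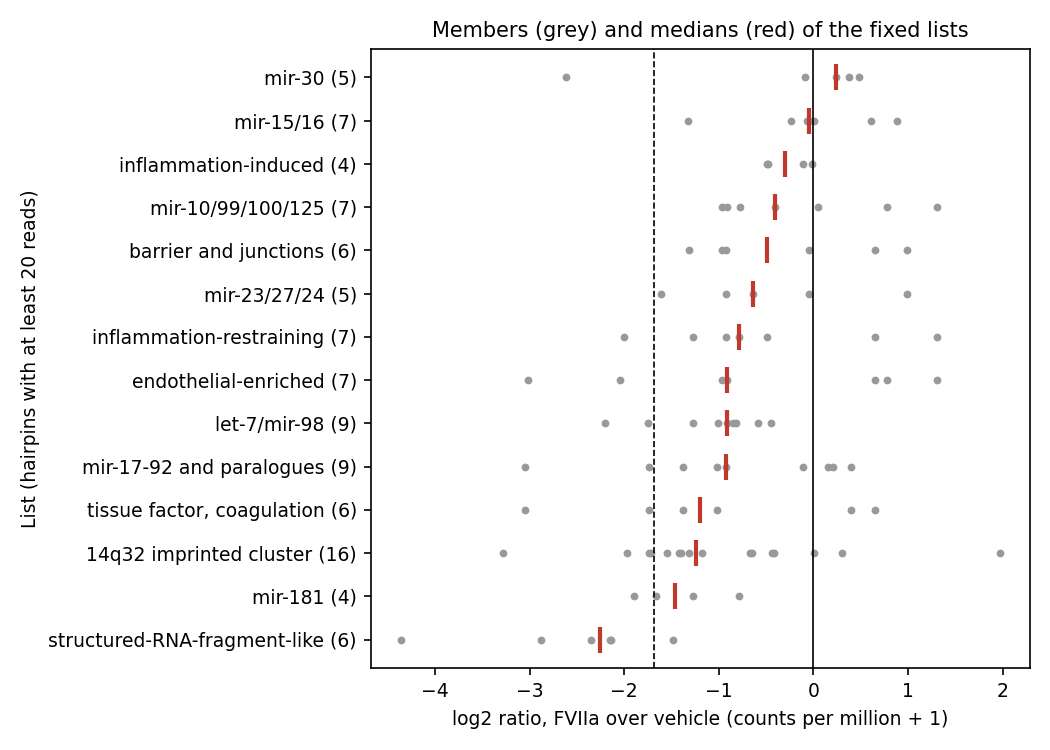
Log2 ratio (FVIIa over vehicle by total count, x axis) of the members (grey points) and the median (red bars) of each fixed hairpin list with a percentile, with the number of measured members in parentheses, a solid line at 0 and a dashed line at the median of all summed hairpins, -1.69. Medians run from -2.25 to 0.23, and on the authors' deposited scale several cross 0, such as that of the mir-15 and mir-16 family from -0.04 to 1.16.

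The last comparison used the mature miRNA counts, the only ones that name an arm. The arm miR-10a-5p had 22 counts in the vehicle library and 34 in the FVIIa library, or 1.88% (1.18 to 2.83) and 10.5% (7.40 to 14.4), a ratio of 5.61 (3.19 to 10.1). On the deposited scale, where mature FVIIa values shift by -0.81 in log2, its ratio was 3.21. Of 12 mature miRNAs with at least 20 reads, 3 were higher, 3 lower and 6 neither, and on the deposited scale 1 was higher and 7 lower. The other two higher ones were miR-548m, with 43 and 28 counts (ratio 2.36, 1.41 to 3.89), and miR-873-5p, with 65 and 42 counts (2.35, 1.55 to 3.51). The lower ones were miR-378c, 3.86-fold lower (1.42 to 14.6), miR-4695-3p, 6.88-fold lower (1.81 to 58.4), and miR-4477a, 8.26-fold lower (1.37 to 337). The most abundant mature row over both libraries was miR-718, with 139 and 25 counts (ratio 0.65, 0.41 to 1.01, not called, but 2.68-fold lower and called on the deposited scale), more than the 36 and 9 counts of its own hairpin. Likewise miR-873-5p exceeded its hairpin, with 6 and 1 counts, as did miR-548m, with 15 and 11, while mir-10a had 41476 and 95185 hairpin counts against 22 and 34 for miR-10a-5p. In the vehicle library 6 of the 11 mature rows with a hairpin row held more counts than that hairpin, so the mature values cannot be read as the arms of the hairpin counts, and the strand and matching rules behind them are not known here. Of the mature members of the fixed lists, miR-10a-5p alone reached 20 reads, so the median of each of the 3 lists that hold it was its own log2 ratio, 2.49. The arm miR-10a-5p was higher under every scaling of the mature counts, though the mature upper quartile lay below 2 reads in the FVIIa library. The mature TMM and DESeq2 factors rest on low counts as well. In the FVIIa library 37 of 384 mature rows had at least 2 reads and 5 had at least 10. A mature row with 0 counts could still hold up to 0.256% of the vehicle table and 0.929% of the FVIIa table.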

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

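The total without 5 hairpins, the list medians from hairpins and the match on GC content were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. Hairpin calls moved most with scaling, from 2 higher and 180 lower by total count to 42 and 79 (TMM and the deposited values), 46 and 70 (DESeq2 size factors), 82 and 35 (upper quartile) and 32 and 96 (total without the 10 most abundant). Without the 5 hairpins there were 1 higher and 202 lower, with a shift of -0.34 in log2. No hairpin called by total count had the opposite call under any of these, but 21 hairpins were higher under one scaling and lower under another. These shifts follow from the factors, which multiply every ratio alike. With no read minimum there were 3 higher and 282 lower, with a minimum of 100 reads 1 and 58, with a fold of 1.5 there were 13 and 200, with a fold of 4 there were 1 and 112, and with the interval wholly beyond 2-fold 1 and 115. Mature calls went from 3 higher and 3 lower to 1 and 7 with TMM, DESeq2, upper-quartile and deposited scaling (shifts of -0.81 for TMM and deposited and -0.86 for the others), 6 and 3 with no minimum, 0 and 0 at a minimum of 100 reads, 1 and 2 at a fold of 4, and 1 and 0 with the interval wholly beyond 2-fold. The ratio of miR-10a-5p, 5.61 by total count, was 3.09 with DESeq2 and upper-quartile factors, and the hairpin mir-10a gave 2.48, or 1.959 without the 5 hairpins. The mature medians of the endothelial-enriched, mir-10 family and inflammation-restraining lists, 2.49 by total count, were 1.63 with DESeq2 and upper-quartile factors, and 1.68 for all 3 with TMM and deposited values. With no minimum they were -10.24, -9.74 and -9.74, values set by members with 0 counts and the pseudocount. From hairpins they were -0.91, -0.40 and -0.78, over 7 members each. At the minimum of 20 reads each mature median was that of miR-10a-5p alone, so the mature and hairpin medians cover unlike sets. The median of the mir-15 and mir-16 hairpins turned from -0.04 to 1.16 (TMM, deposited), 1.302 (DESeq2), 1.958 (upper quartile) and 0.96 (without the 10 most abundant), and that of 14q32 from -1.24 to 0.091 (DESeq2) and 0.74 (upper quartile). Other hairpin medians turned positive on the deposited scale. They were endothelial-enriched (0.29), mir-10 family (0.80), inflammation-restraining (0.42), inflammation-induced (0.90) and barrier (0.71). So did mir-17-92 (0.27), let-7 (0.28) and mir-23, mir-27 and mir-24 (0.56), while coagulation (-0.002), mir-181 (-0.27), 14q32 (-0.05) and structured RNA (-1.08) stayed negative. The mir-30 median turned from 0.23 to -0.11 without the 5 hairpins. The number of lists outside the central 95% was 2 by total count, 1 with random lists matched on GC content as well as abundance, 1 with upper-quartile factors and 0 at a minimum of 100 reads, where 14q32 had too few members and the mir-15 and mir-16 family lay at percentile 88.9. It was 3 with no minimum and 3 with copies kept apart, where the mir-30 family joined the others at percentiles 99.015 and 98.3. Leaving out the most abundant row, the top 1, 10 and 50 hairpins took 15.99%, 63.3% and 87.5% of vehicle and 23.5%, 74.4% and 93.1% of FVIIa counts, and the mature ones 6.29%, 35.98% and 62.4% of vehicle and 12.1%, 50.2% and 76.9% of FVIIa counts. The few mature counts limit these calls, since 12 rows reach 20 reads in the vehicle library and 4 in the FVIIa library.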

Other observations

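The GC test on the number of hairpins with reads, the mir-10a test and both tests on the mature counts were chosen after the results were seen. Fewer hairpins had reads in the FVIIa library, 758 against 1289. With both libraries thinned to 33306 counts outside the 10 most abundant hairpins, the vehicle library still had 1.35 times as many (1.31 to 1.39 over draws), against 1.71 before, so a few hairpins taking most counts may account for part of the gap but not the whole. Among hairpins lowest in GC content, thinned alike, the ratio was 1.34 (1.25 to 1.42), so differences between GC groups do not account for the whole gap. These hairpins still span a range of GC content, so a part due to it stays open. Before thinning, the number with reads in vehicle over FVIIa was 1.73, 1.86 and 1.57 from the lowest to the highest GC group of all hairpins. The gap was thus not widest at the highest GC content, though these values are not matched on counts. The log2 ratio of FVIIa over vehicle did fall with GC content (Spearman's rho across hairpins, which are not independent, -0.59, bootstrap -0.65 to -0.51). Its medians were -0.84, -1.44 and -2.47 from the lowest to the highest GC group of tested hairpins. A GC bias between libraries could give this, though a biological difference with FVIIa stays open and untested. The GC content was that of the whole hairpin, not of the reads, and rho was not matched on abundance. Fragments of other RNAs stay open, since nuclear tRNA was not used here for mir-1260a, mir-1260b, mir-4454, mir-5100 and mir-4286, and the 2 tested hairpins that shared 18 bases with other annotated RNAs (difference of 1.63 in median log2 ratio) are too few.

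The larger share of mir-10a could come from the loss of mir-1260a, mir-1260b, mir-4454, mir-5100 and mir-4286, which held 22.01% of vehicle counts and 1.27% of FVIIa counts. Such a loss leaves ratios among the other hairpins alike. The smallest fold of mir-10a against another abundant hairpin was 1.45 (1.41 to 1.49, against mir-10b), so the loss alone does not account for it. A higher mir-10a content of vesicles released with FVIIa remains a hypothesis from 1 library per group. A GC bias and any difference between preparations stand beside it, and these libraries cannot separate them. The GC content of mir-10a is 39.1%. Of 66 hairpins at 40 to 50% GC, with a median log2 ratio of -0.89, 1 had a higher log2 ratio than mir-10a. That range does not hold mir-10a, which was 1 of only 2 hairpins called higher among 263. Few hairpins in any GC range could thus exceed it, so this count does not bear on a GC bias.

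The mature counts were few and did not mirror the hairpins. The 10 most abundant hairpins supplied 10.5% of mature FVIIa counts (7.40 to 14.4) against 84.3% of hairpin counts, and 2.05% against 68.5% for vehicle, so the mature table is not a thinned sample of the same reads. Reads overhanging the mature sequence might need room in the reference, but among 19 pairs of copies the one with less room had fewer counts in 57.9% (one-sided permutation p = 0.331), which leaves this open. No biological explanation was tested.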
